A study of Rattus norvegicus with 16 samples.

How the data were processed

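RNA-seq libraries were made from the CA1 field of the dorsal hippocampus of 16 male Sprague-Dawley rats aged 14 days, 8 injected with kainate and 8 with saline on postnatal day 7. Per the labels' protocols, CA1 was dissected from 400 µm slices after a recovery of 60 min, and total RNA went into standard Illumina libraries. Trim Galore, RSEM, DESeq2, SAMtools and GATK are named in the submitters' processing notes, without versions. The aligner, genome build and annotation are not given in the sources used here.

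The authors deposited a table of 21698 isoforms with Ensembl identifiers and, for each animal, a value on a log2 scale. From the values, these log2 numbers have a floor that differs between isoforms and is nearly equal between animals, as a regularized logarithm gives. Weakly expressed isoforms therefore have compressed differences. The transform is not named in the sources used here. The same table holds the authors' deposited mean normalized count per isoform, a signal averaged over animals. It also holds the authors' DESeq2 log2 fold change, which from the values is shrunken for weak isoforms, with its standard error, their Wald score, p-value and adjusted p-value. A deposited ratio (fold) equals 2 to the power of the authors' log2 fold change. The adjusted p-value is empty for 5048 isoforms, whose mean normalized count reaches at most 71.7. A second deposited table lists 7 isoforms, and beside them 1334 names in the order of the authors' p-value, down to a p of 0.055. Further deposited tables give p-values and scores of enriched terms, 20 of the Gene Ontology molecular function set and 186 of KEGG, and their scores were not used. A spreadsheet had turned 4 names, and 3 and 107 overlap cells of the term tables, into dates, and these cells were not used.

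The planned count test assumed counts. The per-animal values are log2 values, so limma 3.58.1 in R 4.3.3 (linear models with a mean-variance trend and robust empirical Bayes) was applied to them as deposited, with no added constant and no further filter or normalization. Gene values were the log2 of the summed 2-power values of a symbol's isoforms, for 16602 symbols. Isoform usage was tested with limma's diffSplice (Simes) in 3774 genes with several isoforms. Adjustment was by Benjamini and Hochberg with a threshold of 0.05, and tests were two-sided unless stated. Fold differences are on the deposited, compressed scale. Read totals per library cannot be had from these values, so the depth is unknown and no counting interval is given. In 191 isoforms, 83 of them in genes with several isoforms in the table, the values were identical to those of another isoform in every library, as when reads cannot be told apart. These isoforms are uncertain. No library had values identical to those of another.

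There were 29 gene lists, fixed before the data were examined: AMPA, NMDA and kainate receptor subunits; postsynaptic density; presynaptic vesicle cycle; GABA signalling; voltage-gated ion channels; immediate early genes; metabotropic glutamate receptors with FMRP and mTOR signalling; markers of CA1, CA3 and dentate neurons, cortical layers, interneurons, astrocytes, reactive astrocytes, myelinating oligodendrocytes, their precursors, microglia, vessels, choroid plexus and ependyma, meninges, red blood cells and immature neurons; inflammatory mediators; heat shock; cell death; chromatin modifiers; Alzheimer-related genes; the respiratory chain; and cytosolic ribosomal proteins. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, beside camera with an estimated correlation and fry. The genes to be named were also fixed by rule: isoforms past the threshold with a mean of at least 20 normalized counts, the 10 largest rises and falls and the 5 smallest adjusted p-values per direction, and up to 3 members of each list with the smallest p. No isoform met the first part. A few genes the rule names are not reported here. Gene lengths, used for checks, are gene spans in the RefSeq annotation of GRCr8, matched by symbol or synonym for 14526 symbols (87.5%); none of its coordinates were used.

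The sample titles number the replicates 1 to 8 in both groups. Deviations from the group means correlated between same-numbered libraries in all 8 pairs, with r between 0.127 and 0.781 across isoforms, above a limit of 0.1. The numbers were therefore taken to pair the libraries, and fits with the replicate number as a block are given where they change a call or a count. Most of this pairing follows a split between replicates 1 to 4 and 5 to 8: with that split removed, r ran from -0.349 to 0.667 with a median of 0.169, and 9 of 16 libraries correlated best with the library of their own number. With the split removed, pairs 1 and 8 had r of -0.349 and -0.112, below the limit of 0.1. The labels give no batch and do not say that same-numbered rats were matched. Within each group the replicate numbers follow the rising order of the animal numbers in the titles. The pairing is therefore an assumption, on which the block fits, the counts of pairs and the sign flips rest. Unless stated, standard errors (SE) of limma differences are from the fit without the block and include the difference between replicates 1 to 4 and 5 to 8. With the block some were smaller, as for the Fry isoform (0.087 against 0.37), and some larger, as for Ccdc153 (0.12 against 0.11). Across isoforms, the authors' Wald score correlated with limma's statistic at 0.931 without the block and 0.984 with it. With a term for replicates 1 to 4 against 5 to 8 in place of the block it was 0.971.

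On simulated values with the same means, residual spread and difference between replicates 1 to 4 and 5 to 8, limma without the block recovered 68.7% of isoforms changed by 0.25 on the log2 scale, 89.6% of those changed by 0.5 and 100% of those changed by 1, among 21698 isoforms; with the block it recovered 79.1%, 91.0% and 100%. The usage test without the block recovered 47.8%, 89.6% and 97.0% at these sizes among 3774 genes, and camera called 8 of 9 lists raised by 0.05 among 29. False calls were 2 isoforms without the block and 6 with it, 4 usage genes without the block and 1 list. The isoforms changed by these sizes, 67, 67 and 66 in number, were changed together, which eases the adjustment for the smallest size. The recovery rates therefore do not show that changes of 0.25 are absent from the real data. Noise was drawn independently for each gene, with no pair effect, whereas the estimated correlation of the real channel list was 0.455. Camera with an estimated correlation also recovered 8 of 9 lists, so the simulation does not speak for the preset correlation. Alternatives were limma without trend, quantile normalization, a stricter filter, sample weights, the block, other thresholds and each library left out in turn. Added after the data were seen were a term for replicates 1 to 4 against 5 to 8, each of these sets of libraries alone, both libraries of each replicate number left out, a correction for gene length, a library score as a covariate, the library means of other lists as covariates, sign flips of the list means within pairs and a Fisher's exact test of the lists. Figures were drawn with matplotlib 3.10.9.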

Results

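Gene expression was measured in CA1, the output field of the hippocampus proper, 7 days after a single seizure episode early in life. Male rat pups received 2 mg/kg of kainate, a glutamate receptor agonist that provokes seizures, under the skin on postnatal day 7, or saline, and were killed on postnatal day 14. There were 8 kainate and 8 control libraries, and only the separate animal numbers in the sample titles show that each came from a different rat. The table held 21698 isoforms of 16602 gene symbols, of which 20008 were protein coding. In the authors' deposited table the median isoform had a mean normalized count of 509 and the lowest had 3.35; the depth of each library is unknown.

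The first principal component of all isoforms held 45.3% of the variance and separated replicates 1 to 4 from replicates 5 to 8 of both groups, with scores of -23.2 to -4.31 against 5.88 to 17.4 (exact two-sided permutation test, n = 8 libraries each, p = 0.000155). It did not separate kainate from control (exact permutation test, n = 8 per group, p = 0.539). The cut between replicates 4 and 5 was chosen after the data were seen, so the first of these p-values only describes the separation. By limma, 8426 isoforms differed between these 2 sets of libraries at an adjusted p under 0.05, 4282 higher and 4144 lower in replicates 1 to 4. The median absolute difference between the sets was 0.072 on the log2 scale, against 0.023 between kainate and control. Each set held 4 libraries of each group.

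**Figure D1:**
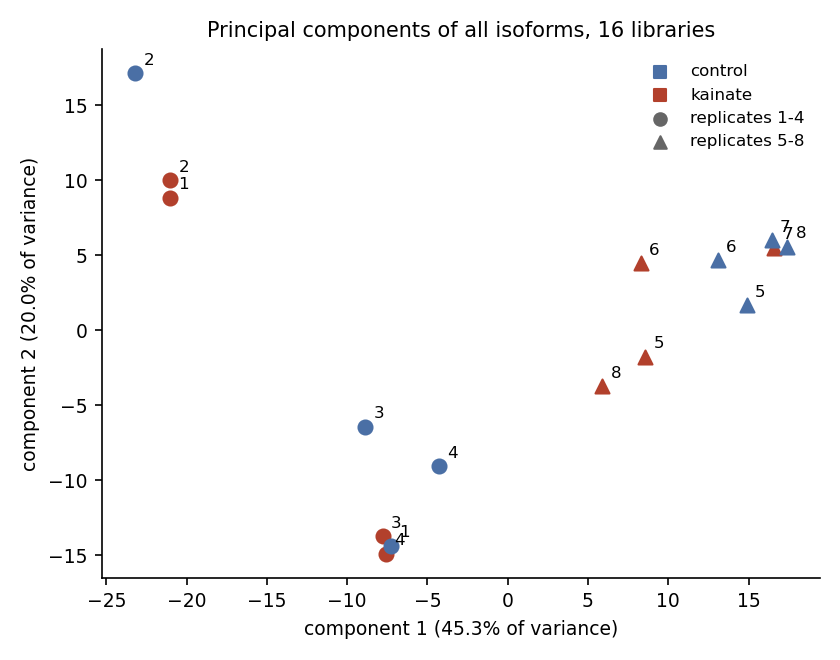
Scores of the 16 libraries on the first and second principal components of all isoforms, the first with 45.3% of the variance. Colour gives the group, shape the set of replicates and the number the replicate, and replicates 1 to 4 lie at or below -4.31 on the first component and replicates 5 to 8 at or above 5.88, whatever their group.

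The first comparison asked which isoforms differed in CA1 a week after kainate seizures. The authors' deposited table lists 7, of which 6 were higher and 1 lower after kainate, and 6 of the 7 are described here. An isoform of Nedd4, a ubiquitin ligase, was at 1.35 times its control level in the authors' deposited table (log2 fold change 0.43, SE 0.070, adjusted p = 1.29e-05). The authors' deposited table gives ratios of 1.10 for Nr3c2, the mineralocorticoid receptor (adjusted p = 0.00707), 1.14 for Usp45, a deubiquitinase (adjusted p = 0.0384), 1.24 for Cep295, a centriole protein (adjusted p = 0.0216), and 1.23 for Fry, a microtubule-associated protein (adjusted p = 0.0439). The lower isoform belonged to Sepw1, selenoprotein W, with a ratio of 0.888 and an adjusted p of 0.00707 in the authors' deposited table.

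The chromosome and gene start of these 6, in the authors' deposited table, are 8 and 79323408 for Nedd4 (ENSRNOT00000090258), 1 and 77803475 for Sepw1 (ENSRNOT00000080422), 19 and 34448289 for Nr3c2 (ENSRNOT00000052018), 8 and 13871213 for Cep295 (ENSRNOT00000029634), 5 and 35916804 for Usp45 (ENSRNOT00000083132), and 12 and 5573729 for Fry (ENSRNOT00000041365). The build of these positions is not given in the sources used here.

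Per library, the Nr3c2 isoform had a mean deposited log2 value of 12.09 ± 0.11 (SD, n = 8) after kainate. This was 0.094 ± 0.049 (SE, n = 8 per group) above the controls, and kainate was the higher in 8 of 8 same-numbered pairs. The same held in 8 of 8 pairs for the isoforms of Cep295 (8.32 ± 0.23 against 7.99 ± 0.29, SD, n = 8) and Usp45 (10.39 ± 0.15 against 10.26 ± 0.16, SD, n = 8). It also held in 8 of 8 pairs for the isoform of Fry (9.82 ± 0.75 against 9.35 ± 0.80, SD, n = 8). The Sepw1 isoform was the lower after kainate in all 8 pairs, at 13.32 ± 0.23 against 13.45 ± 0.21 (SD, n = 8). The isoforms described here were picked by the authors' test on the same libraries, whose score correlated at 0.984 with the replicate-block statistic. The counts of pairs are therefore no separate support. The Nedd4 isoform was the higher in 6 of 8 pairs, at 8.42 ± 1.77 against 8.04 ± 1.37 (SD, n = 8). Its mean was 9.69 in replicates 1 to 4, where kainate exceeded control by 0.75 (exact permutation test, n = 4 per group, p = 0.0571), and 6.78 in replicates 5 to 8, where the difference was 0.0054 (exact permutation test, n = 4 per group, p = 0.800). With both libraries of replicate 2 left out, the difference over the remaining libraries was 0.28 for the Nedd4 isoform, 0.49 for the Fry isoform and -0.12 for the Sepw1 isoform, against 0.38, 0.46 and -0.12 with all libraries. Without kainate replicate 2 alone, which leaves its control unpaired, these were 0.11, 0.28 and -0.076. The largest with 1 library left out were 0.62 for Nedd4, without control replicate 3, and 0.67 for Fry and -0.17 for Sepw1, both without control replicate 2.

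**Figure D2:**
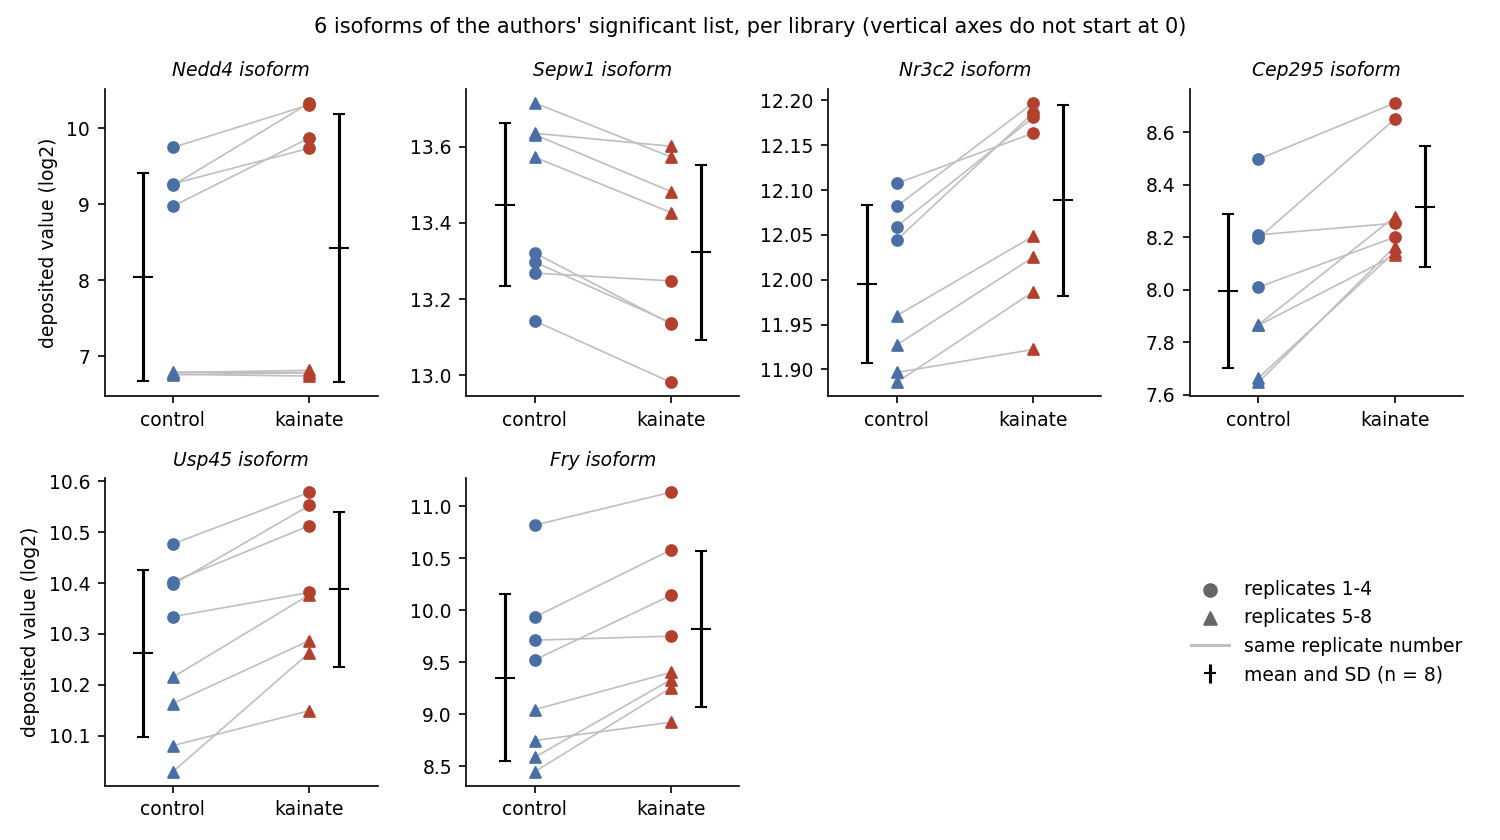
Deposited log2 values of 6 isoforms in each library, control on the left and kainate on the right of each panel; lines join libraries of the same replicate number, and bars give the mean and SD of 8 libraries. Kainate lies above control in 8 of 8 pairs for Nr3c2, Cep295, Usp45 and Fry and below it in 8 of 8 for Sepw1, while the Nedd4 isoform lies between 6.74 and 6.81 in replicates 5 to 8 of both groups. The isoforms were picked by the authors' test on these same libraries.

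Tested with limma on the deposited values, none of the 7 passed: the adjusted p was 1.00 for each without the replicate block and 0.797 for each with it. Without the block 0 of 21698 isoforms passed, 325 had an unadjusted p under 0.05 (142 higher, 183 lower) and 1085 would by chance. That fit leaves the split of replicates described above in its residual spread, so its low count is no evidence that differences are absent. A term for that split was added after the data were seen. With it 0 passed and 1044 had an unadjusted p under 0.05, 697 higher and 347 lower. With the replicate block 0 passed and 1330 had an unadjusted p under 0.05, 875 of them higher after kainate and 455 lower. In the authors' deposited table, 1228 isoforms had an unadjusted p under 0.05, 847 higher and 381 lower.

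Summed over isoforms, the genes behind the list showed smaller differences. Total Nedd4, whose other isoform (ENSRNOT00000088391) was at 15.04 ± 0.061 against 15.03 ± 0.069 (SD, n = 8), differed by 0.022 ± 0.040 (SE, n = 8 per group). Totals differed by 0.0089 ± 0.062 for Cep295, 0.072 ± 0.080 for Fry, 0.070 ± 0.055 for Usp45 and -0.093 ± 0.078 for Sepw1 (SE, n = 8 per group), and Nr3c2 had 1 isoform in the table. By limma without the block 0 of 16602 genes passed at an adjusted p under 0.05. In that fit, which leaves the split of replicates in its residual spread, 230 had an unadjusted p under 0.05, against 830 by chance. With a term for the split 0 passed and 841 had an unadjusted p under 0.05 (537 higher, 304 lower). With the replicate block 0 passed and 1096 did.

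Isoform usage, the mix of isoforms within a gene, was compared next. Shank2, a scaffold of the postsynaptic density with 7 isoforms in the table, had the smallest p, with an unadjusted p of 0.000371 and an adjusted p of 1.00 by limma's diffSplice. By limma 0 of 3774 genes passed and 88 had an unadjusted p under 0.05. With the replicate block 0 passed and 257 did, led by Pfkfb4, Abcf2, Arpp21, Itgae and Shank2 at an adjusted p of 0.105 each. Without control replicate 1, Shank2 alone passed (adjusted p = 0.0213, limma), and without both libraries of replicate 1 it did not (adjusted p = 0.0582). Its isoform ENSRNOT00000092357 was 0.43 ± 0.18 (SE, n = 8 per group) higher after kainate in the fit of all libraries. That isoform was singled out after its values were seen.

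The third comparison took the fixed gene lists, to ask which groups of genes moved together. By camera with the preset correlation, genes of voltage-gated channels, of the postsynaptic density and of GABA and glutamate receptors lay higher after kainate relative to other genes. Markers of dentate granule cells did too, while myelin genes lay lower. With an estimated correlation no list was called (smallest camera adjusted p = 0.271). With the library means of the dentate and myelin lists as covariates, chosen after the data were seen, none of the channel, postsynaptic, GABA, receptor subunit and metabotropic lists was called, and the channel median was 0.012 (camera adjusted p = 0.731). Both covariates are themselves called lists, so they can take out a group difference whatever its cause. Among 21 pairs of other called lists used as covariates, 13 left at most 1 of the 5 lists called. Of 35 measured voltage-gated ion channel genes, 32 had higher means, with a median difference of 0.069 on the log2 scale (camera adjusted p = 1.46e-08, or adjusted p = 0.351 with an estimated correlation). Without both libraries of replicate 8 the channel median was 0.042. Cacna2d1, an auxiliary calcium channel subunit, differed by 0.14 ± 0.076, and Kcnh7, a potassium channel, by 0.17 ± 0.099 (SE, n = 8 per group). In the postsynaptic density list, 23 of 26 genes were higher, with a median of 0.051 (camera adjusted p = 1.09e-06, or adjusted p = 0.271 with an estimated correlation). Without both libraries of replicate 8 this median was 0.032. Its scaffold genes Dlgap1, Dlg3 and Dlg2 differed by 0.060 ± 0.033, 0.053 ± 0.031 and 0.091 ± 0.062 (SE, n = 8 per group).

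In GABA signalling, 19 of 24 genes were higher, with a median of 0.028 (camera adjusted p = 0.000994, or adjusted p = 0.281 with an estimated correlation). The median was 0.046 in replicates 5 to 8 alone and 0.018 with the length trend removed. The receptor subunit genes Gabrg3 and Gabrb2 differed by 0.099 ± 0.059 and 0.15 ± 0.091 (SE, n = 8 per group). In the fit with the replicate block, which rests on the assumed pairing, these SEs were 0.029 and 0.042. Adjusted over the list alone, 0 passed without the replicate block and 4 passed with it, among them Gabrb1, Gabrb2 and Gabrg3, at a limma adjusted p of 0.0286 each. The list of AMPA, NMDA and kainate receptor subunits had 16 of 20 genes higher and a median of 0.021 (camera adjusted p = 0.0118, or adjusted p = 0.281 with an estimated correlation), with Gria3 at 0.093 ± 0.049, Cacng3 at 0.096 ± 0.056 and Gria2 at 0.079 ± 0.070 (SE, n = 8 per group). It lost its call without kainate replicate 8 (camera adjusted p = 0.0642) or control replicate 5 (adjusted p = 0.0549), and in replicates 5 to 8 alone (adjusted p = 0.115). It also lost it without both libraries of replicate 1 (adjusted p = 0.0672) or of replicate 8 (adjusted p = 0.124). Its median was 0.014 and 0.013 without the first and second of those single libraries, 0.014 and 0.011 without those pairs, and 0.033 without kainate replicate 7 and 0.032 without control replicate 6. Metabotropic glutamate receptor, FMRP and mTOR genes were higher in 22 of 34 cases, with a median of 0.027 (camera adjusted p = 0.0106, or adjusted p = 0.281 with an estimated correlation), and one of 0.017 in replicates 1 to 4 alone. Grm2 and Grm5 differed by 0.19 ± 0.12 and 0.11 ± 0.072 (SE, n = 8 per group). Without both libraries of replicate 8 the median of the metabotropic list was 0.011 (camera adjusted p = 0.108), and without kainate replicate 7 it was 0.042. With a length trend removed from each library, the calls of this list (camera adjusted p = 0.102) and of the receptor subunit list (adjusted p = 0.288) ended.

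Immediate early genes, which neurons switch on within minutes of activity, had 26 of 31 members higher and a median of 0.050 (camera adjusted p = 0.000375, or adjusted p = 0.382 with an estimated correlation). Npas4 differed by 0.23 ± 0.085, Inhba by 0.10 ± 0.047 and Egr3 by 0.082 ± 0.048 (SE, n = 8 per group). The call was lost without control replicate 1, with a median of -0.0050 (camera adjusted p = 0.299), and without both libraries of replicate 1, with a median of 0.021 (adjusted p = 0.0785). The median was between 0.026 and 0.032 without kainate replicate 2, 6, 7 or 8 or control replicate 4, and 0.028 without both libraries of replicate 2, each still called. Replicates 1 to 4 alone gave a median of 0.080 (camera adjusted p = 0.000353) and replicates 5 to 8 alone 0.018 (adjusted p = 0.296).

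Markers of dentate granule cells, the neurons across the hippocampal fissure, had 12 of 13 members higher and a median of 0.060 (camera adjusted p = 5.90e-05, or adjusted p = 0.271 with an estimated correlation). Its median was 0.035 without kainate replicate 3, 0.038 without control replicate 8 and 0.040 without both libraries of replicate 3. It was 0.038 with the length trend removed, 0.040 with the library score as a covariate, and 0.085 in replicates 1 to 4 against 0.033 in replicates 5 to 8. Prox1, the transcription factor that marks them, differed by 0.23 ± 0.10, Stxbp6 by 0.14 ± 0.066 and Pdzd2 by 0.13 ± 0.065 (SE, n = 8 per group). CA1 markers had 8 of 12 members higher and a median of 0.042 and did not pass (camera adjusted p = 0.127, or 0.00548 in replicates 1 to 4 alone), with Wfs1 at 0.10 ± 0.061 (SE, n = 8 per group). The CA1 median was 0.015 without both libraries of replicate 2 and 0.072 without those of replicate 1. CA3 markers had a median of -0.017 (camera adjusted p = 0.370, or 0.0425 in replicates 1 to 4 alone). Cortical layer markers had a median of 0.020 (camera adjusted p = 0.0392, or 0.0508 with the replicate block, or adjusted p = 0.271 with an estimated correlation), with Tbr1 at 0.080 ± 0.058 and Rspo1 at 0.075 ± 0.057 (SE, n = 8 per group).

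Myelin genes lay lower after kainate as a group. All 24 measured members had lower means, with a median of -0.091 (camera adjusted p = 1.46e-08, or adjusted p = 0.281 with an estimated correlation), and the medians within replicates 1 to 4 and 5 to 8 were -0.11 and -0.081. The median was -0.059 without kainate replicate 1 and -0.036 without both libraries of replicate 1 (adjusted p = 0.0114). Mbp, a main protein of compact myelin, differed by -0.14 ± 0.070, Cnp by -0.12 ± 0.050 and Cldn11 by -0.14 ± 0.070 (SE, n = 8 per group). Oligodendrocyte precursor markers did not pass, with a median of -0.019 (camera adjusted p = 0.475), although they did in replicates 1 to 4 alone, with a median of -0.066 (adjusted p = 0.000143). Choroid plexus and ependymal markers had 9 of 11 members lower and a median of -0.12 (camera adjusted p = 0.000260, or adjusted p = 0.281 with an estimated correlation). Their members with the smallest p were genes of cilia and ciliated cells, Ccdc153 at -0.26 ± 0.11, Cfap126 at -0.15 ± 0.070 and Tmem212 at -0.12 ± 0.058 (SE, n = 8 per group), and the call ended in replicates 5 to 8 alone (camera adjusted p = 0.188). Without both libraries of replicate 2 the median was -0.062 (adjusted p = 0.0297).

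Of the respiratory chain genes, 78 of 79 had lower means after kainate, with a median of -0.049 (camera adjusted p = 1.23e-08, or adjusted p = 0.399 with an estimated correlation). Of the cytosolic ribosomal protein genes, 77 of 80 did, with a median of -0.059 (camera adjusted p = 1.03e-08, or adjusted p = 0.399 with an estimated correlation). Cox5a differed by -0.058 ± 0.036, Atp5j by -0.062 ± 0.037, Rpl36a by -0.10 ± 0.058 and Rps27 by -0.11 ± 0.073 (SE, n = 8 per group). The medians were -0.017 and -0.021 in replicates 1 to 4 against -0.078 and -0.094 in replicates 5 to 8, for the respiratory and ribosomal lists. The respiratory median was -0.028 without kainate replicate 4, -0.027 without control replicate 7, -0.032 without control replicate 8, -0.031 without both libraries of replicate 8 and -0.075 without kainate replicate 7. The ribosomal median was -0.032 without control replicate 7 and -0.027 without both libraries of replicate 8.

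**Figure D3:**
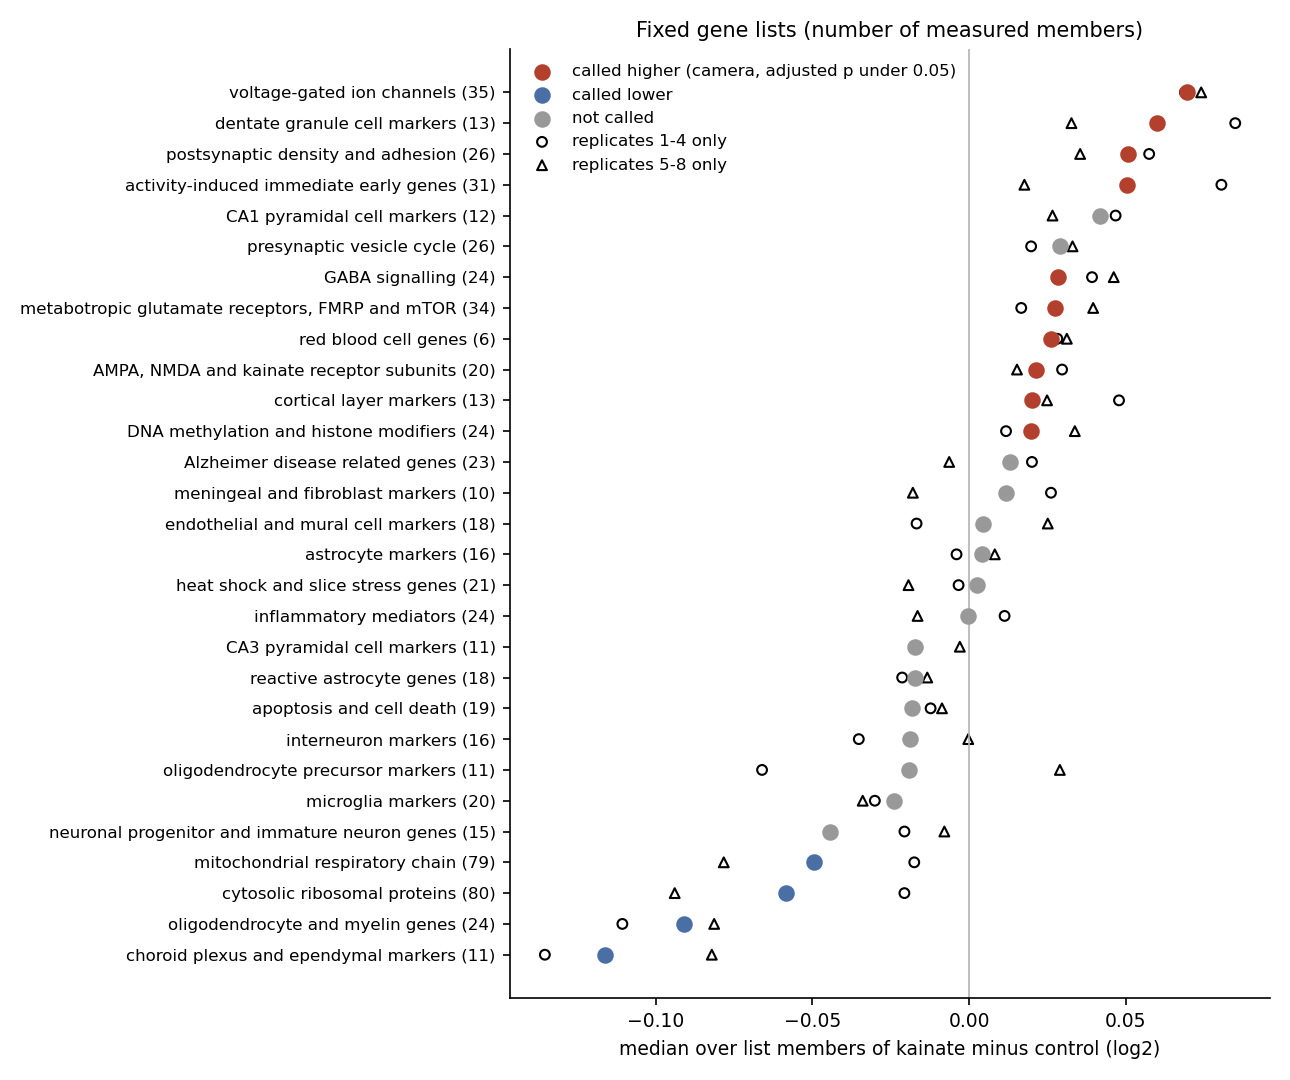
Median difference between kainate and control over the members of each of the 29 gene lists (log2, horizontal axis); filled points use all 16 libraries and are coloured by the camera call, open circles use replicates 1 to 4 and open triangles replicates 5 to 8. Medians run from -0.12 for choroid plexus and ependymal markers to 0.069 for voltage-gated ion channels.

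In total, camera with the preset correlation called 14 of 29 lists, 10 higher and 4 lower. With an estimated correlation 0 were called (smallest adjusted p = 0.271), and fry, which asks whether a list's genes move on balance in one direction, also called 0 (smallest adjusted p = 0.565). No member of any list passed on its own over all genes: the limma adjusted p of each gene named from the lists was 1.00 without the replicate block, and none passed with it. Exact two-sided permutation tests of the list means per library (n = 8 per group) gave p between 0.0586 and 0.993 over the 29 lists, with a smallest Benjamini-Hochberg adjusted p of 0.512. These tests ignore the pairing. Exact two-sided sign flips within the 8 numbered pairs, chosen after the data were seen, gave p from 0.0156, for GABA signalling with 7 of 8 pairs higher, to 0.992. Of the 29 lists, 5 had a p under 0.05 (GABA, channels, receptor subunits, metabotropic and dentate), and the smallest adjusted p was 0.272. Among the other lists called by camera the sign-flip p ran from 0.0625 for choroid plexus and ependyma to 0.461 for red blood cells. It was 0.109 for the postsynaptic list, 0.164 for myelin, 0.203 for the respiratory chain, 0.227 for ribosomal proteins and 0.344 for immediate early genes. Of the 14 called lists, 8 were also called, in the same direction, in replicates 1 to 4 alone and in replicates 5 to 8 alone. The 14 were picked on these same libraries, so this is no separate support. The preset correlation also called lists in 97 of 99 other random splits of the libraries.

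**Figure D4:**
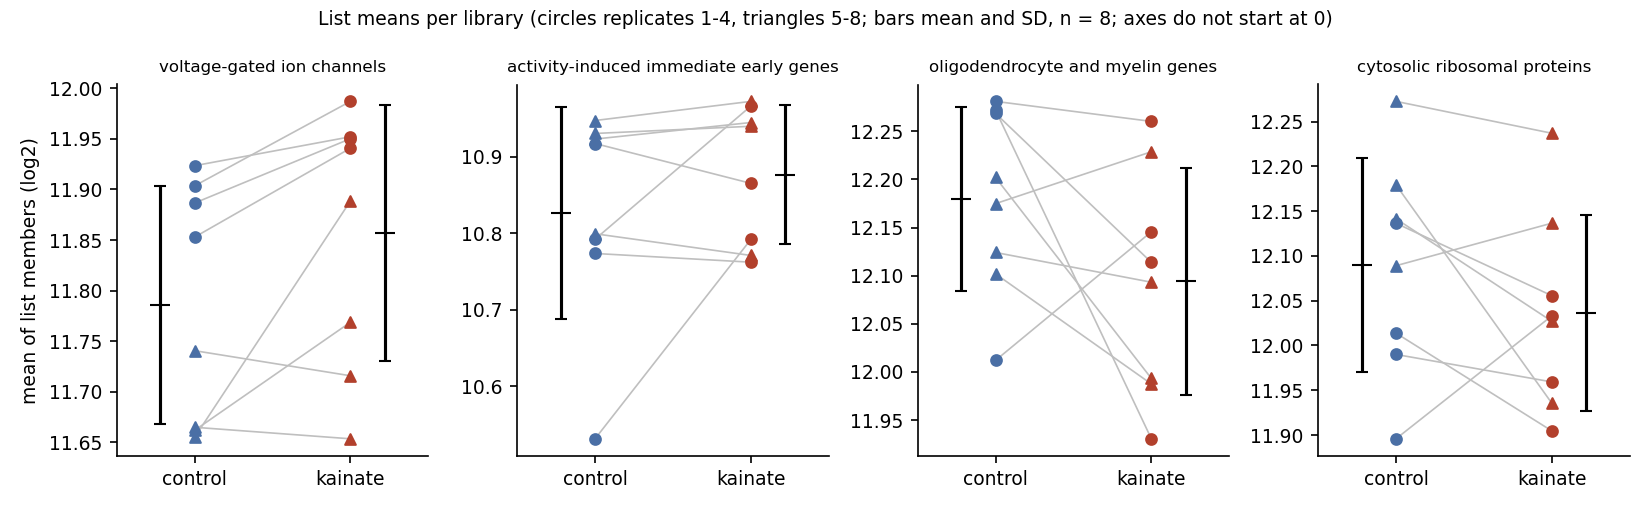
Mean log2 value over the members of 4 lists in each library; lines join libraries of the same replicate number and bars give the mean and SD of 8 libraries. The groups overlap in each panel: 11.86 ± 0.13 after kainate against 11.79 ± 0.12 for voltage-gated channels, 10.88 ± 0.090 against 10.83 ± 0.14 for immediate early genes, 12.09 ± 0.12 against 12.18 ± 0.096 for myelin genes and 12.04 ± 0.11 against 12.09 ± 0.12 for ribosomal proteins.

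Lists of glia, vessels and injury mostly did not pass. Microglia markers had 15 of 20 members lower and a median of -0.024 (camera adjusted p = 0.101, or 0.0216 with the replicate block, or adjusted p = 0.492 with an estimated correlation and the block), with Ctss at -0.092 ± 0.040 (SE, n = 8 per group). The microglia list was called lower without both libraries of replicate 2, 3, 4 or 5 (camera adjusted p of 0.0254 to 0.0464). Reactive astrocyte genes had a median of -0.017 (camera adjusted p = 0.212), with Vim at -0.12 ± 0.066, and astrocyte markers one of 0.0040 (adjusted p = 0.726), with S100b at -0.076 ± 0.041 (SE, n = 8 per group). The reactive astrocyte list was called lower without both libraries of replicate 5 (camera adjusted p = 0.0476). Inflammatory mediators had 12 of 24 members higher (camera adjusted p = 0.987), and Il1b, weakly expressed with a control mean of 3.52, differed by -0.020 ± 0.0072 (SE, n = 8 per group). Medians were -0.018 for cell death (camera adjusted p = 0.260), 0.0024 for heat shock (adjusted p = 0.730), 0.0044 for vessels (adjusted p = 0.410) and 0.012 for meninges (adjusted p = 0.954). Without both libraries of replicate 3 the vessel list was called higher, with a median of 0.025 (camera adjusted p = 0.0101). Without those of replicate 2 its median was -0.0054 and the meningeal median -0.014. With all libraries, the astrocyte, heat shock and meningeal lists had a median above 0 and a mean and test direction below it. For inflammatory mediators the median and test were below 0 and the mean above.

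Among the remaining lists, presynaptic genes had 17 of 26 members higher and a median of 0.029 (camera adjusted p = 0.0940, or 0.0279 with the replicate block, or adjusted p = 0.492 with an estimated correlation and the block), with Syt7 at 0.089 ± 0.061 (SE, n = 8 per group). The presynaptic list was called higher without both libraries of replicate 2, 3, 5 or 6 (camera adjusted p of 0.0171 to 0.0386). Without those of replicate 8 its median was 0.012 (camera adjusted p = 0.611). Interneuron markers had a median of -0.019 (camera adjusted p = 0.315), and in replicates 1 to 4 alone one of -0.035 (adjusted p = 0.0270). Pvalb, the parvalbumin of fast-spiking interneurons, differed by -0.12 ± 0.049 (SE, n = 8 per group) and was lower in 8 of 8 pairs. It was the only interneuron marker to pass adjusted over the list alone with the replicate block (limma adjusted p = 0.0406). Adjusted over all genes, Pvalb did not pass with the block. Chromatin modifiers had a median of 0.020 (camera adjusted p = 0.0458, or adjusted p = 0.399 with an estimated correlation), with Tet3 at 0.13 ± 0.091 and Hdac9 at 0.081 ± 0.066 (SE, n = 8 per group), and red blood cell genes one of 0.026 over 6 members (camera adjusted p = 0.0392, or adjusted p = 0.399 with an estimated correlation), with Hba-a2 at 0.083 ± 0.11 (SE, n = 8 per group). Immature neuron genes had a median of -0.044 (camera adjusted p = 0.194) and Alzheimer-related genes one of 0.013 (adjusted p = 0.310). The immature neuron list was called lower without both libraries of replicate 6 (camera adjusted p = 0.0397). Its median was -0.013 without those of replicate 8 and -0.018 without those of replicate 1. Leaving out 1 library ended the call of the cortical list for kainate replicates 1, 4, 6, 7 and 8 and control replicates 1 to 4 (adjusted p of 0.0542 to 0.128). It ended the call of the red blood cell list for kainate replicates 1, 7 and 8 and control replicates 1 to 6 (0.0534 to 0.439), and that of the chromatin list for kainate replicates 1 to 5 and 8 and control replicates 5 to 8 (0.0534 to 0.215). With any 1 library left out their medians ran from 0.0094 to 0.028, from 0.012 to 0.049 and from 0.0091 to 0.036, in that order, with the lowest without control replicate 2, kainate replicate 7 and kainate replicate 4 and the highest without control replicate 6, kainate replicate 4 and control replicate 1. Without both libraries of replicate 1 they were 0.010, 0.016 and 0.043, and without those of replicate 8 they were 0.013, 0.016 and 0.013. The cortical median was 0.048 in replicates 1 to 4 alone, and the chromatin median 0.012 there and 0.034 in replicates 5 to 8 alone.

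The authors' enriched terms name the same kinds of gene, but come from the same libraries and are no separate support. In the authors' deposited table of molecular functions, 18 of 20 terms had an adjusted p under 0.05, led by gated channel activity with 20 genes, of which 19 were higher and 1 lower after kainate (adjusted p = 0.000429). In the authors' deposited table of KEGG pathways, 10 of 186 did, led by retrograde endocannabinoid signalling with 11 genes, all higher (adjusted p = 0.000296), and dopaminergic synapse with 12, all higher (adjusted p = 0.000296). All 138 genes named in these terms had an isoform with an unadjusted p of 0.0099 or less in the authors' deposited table, where 313 isoforms had a p under 0.01, 255 higher and 58 lower, against 217 by chance.

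By one-sided Fisher's exact tests against all 16602 symbols, chosen after the data were seen, 4 of the fixed lists were over-represented among the 301 symbols with such an isoform. Voltage-gated ion channels had 9 of 35 members there against 0.635 by chance (adjusted p = 2.54e-07), immediate early genes 4 of 31 (adjusted p = 0.0309), metabotropic receptor and mTOR genes 4 of 34 (adjusted p = 0.0309) and glutamate receptor subunits 3 of 20 (adjusted p = 0.0388). Random lists matched on gene length held as many members in a share of 0.0001 of 10000 draws for channels and for immediate early genes, the smallest share these can give. The share was 0.023 for metabotropic receptor and mTOR genes and 0.0879 for glutamate receptor subunits. Both tests take genes as independent. Camera with an estimated correlation, 0.455 for channels and 0.236 for immediate early genes, called none of these 4 lists (adjusted p = 0.351, 0.382, 0.281 and 0.281, in the order given). Of the 9 channel genes, 8 were Kcnma1, Kcnq5, Cacna2d1, Kcna1, Cacna1e, Kcnd3, Cacna1b and Kcnq3, with ratios of 1.12 to 1.18 in the authors' deposited table. The potassium channel genes Kcnq3 and Kcnq5 had ratios of 1.14 and 1.18 in the authors' deposited table, each with an adjusted p of 0.258 or more.

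The difference between kainate and control also followed gene length. Across 14526 genes, which are not independent replicates, Spearman's rho between the difference and the gene span was 0.347; it was 0.125 within replicates 1 to 4 and 0.405 within replicates 5 to 8. In 10 classes of rising length, the shortest genes had a median difference of -0.015 and the longest 0.026. The difference between replicates 1 to 4 and 5 to 8 had a rho of 0.451 with length. Per library, the rho of a library's deviation with length averaged 0.055 ± 0.34 after kainate and -0.056 ± 0.39 in controls (SD, n = 8; exact two-sided permutation test, p = 0.547).

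**Figure D5:**
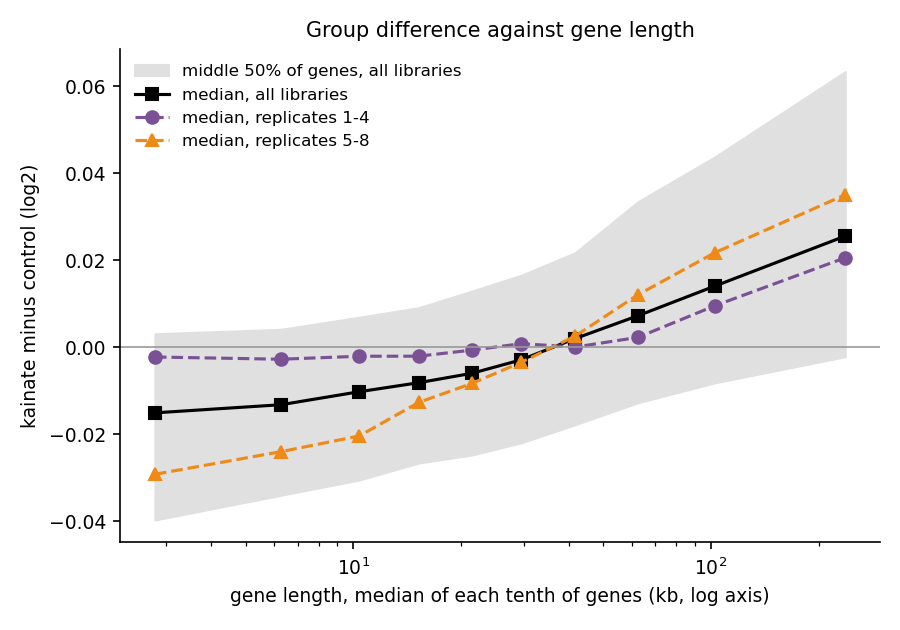
Median difference between kainate and control (log2) in each of 10 length classes of 14526 genes ordered by gene span (log axis, kb); squares use all libraries with the interquartile range over genes shaded, circles use replicates 1 to 4 and triangles replicates 5 to 8. The median runs from -0.015 in the shortest class to 0.026 in the longest.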

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

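The groups below were picked by a test fixed before the data were examined, in which the gap of a group's highest or lowest library to its nearest neighbour takes more than a set share of the group's range. It picked 8 of 186 groups of 8 libraries, where chance gives about 9, so these values are given without an explanation. The immediate early gene list had a mean of 10.53 in control replicate 1, where the other controls lay between 10.77 and 10.95, and this is the library without which that list lost its call. The CA1 marker list had a mean of 11.50 in control replicate 2, against 11.64 to 11.71 in the other controls. The CA3 marker list had a mean of 10.01 in kainate replicate 7, against 9.87 to 9.93, and the meningeal list 8.88 in kainate replicate 3, against 9.01 to 9.11. Among single genes, Dcn, which is on both the CA1 and the meningeal list, was at 10.94 in control replicate 2, against 11.47 to 11.62 in the other controls. The low Dcn and the low CA1 mean in that library are therefore not separate observations. S100b, an astrocyte gene, was at 15.04 in the same library, against 14.86 to 14.92 in the other controls. Fam84b was at 6.66 in control replicate 4, against 6.75 to 6.79, and Ptk2b at 14.28 in kainate replicate 4, against 14.33 to 14.38.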

How the results depend on the processing

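The term for replicates 1 to 4 against 5 to 8, these sets alone, pairs left out, the length correction, the library score, the covariates and the block with an estimated correlation were chosen after the data were seen. The count of isoforms and of genes called by limma was 0 under every setting run. The count of lists, 14, fell to 0 with an estimated correlation, to 0 with fry, to 0 with the replicate block and an estimated correlation, to 3 with the library means of the dentate and myelin lists as covariates and to 9 in replicates 5 to 8 only. Other settings gave 10 with gene length removed, 12 with the highest-mean isoform of each gene, 13 with the term for replicates 1 to 4 against 5 to 8 and 15 in replicates 1 to 4 only. The replicate block gave 0 isoforms, 0 genes, 0 usage genes and 15 lists; it ended the cortical call, added the presynaptic and microglia lists and changed no other call. Leaving out 1 library gave 10 to 14 lists, with 10 without kainate replicate 8, and 0 to 1 usage genes, with 1 (Shank2) without control replicate 1. Leaving out both libraries of a replicate number gave 9 to 17 lists, with 9 without replicate 8 and 17 without replicate 3, and 0 usage genes. In the authors' deposited table, thresholds of 0.01 and 0.1 give 3 and 11 isoforms and a threshold of 0.1 gives 17 KEGG terms. Over the single lists and settings, 806 values stayed on their side of the threshold, 113 calls were lost, 26 were gained and 68 times an uncalled list changed its test direction. Of the called lists 2 reversed their test direction, both uncalled with those covariates: the dentate list, whose median was 0.0059 and which is itself a covariate, and the red blood cell list (-0.027). Further, the immediate early median went to -0.0050 without control replicate 1 and to -0.0037 with those covariates. The receptor subunit median went to -0.013 with those covariates. Among named genes, only Cacng3 and Ptk2b, uncalled, changed sign, in replicates 5 to 8 only (-0.026 and -0.015). The causes were not tested. The count tools and their size factors were not run because no counts were used, nor was another added constant, since the values are already logarithms. Unknown depth leaves open how much of the spread of weak isoforms is counting error.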

Other observations

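The tests of the Nedd4 total, of the receptor subunit, chromatin, metabotropic, GABA and cortical lists against gene length, of the dentate and higher neuronal lists against dissection, and of splits for isoforms, genes and usage were chosen after the result was seen. Several activity-dependent genes had an isoform with an unadjusted p under 0.01 in the authors' deposited table. Nr4a2, Ptgs2, Npas4 and Inhba had log2 fold changes of 0.17, 0.13, 0.21 and 0.18 in the authors' deposited table, with DESeq2 adjusted p of 0.150 to 0.515. The NMDA receptor subunits Grin2a and Grin2b also had such an isoform, with log2 fold changes of 0.20 each in the authors' deposited table. Mdm2, a regulator of p53, was lower after kainate in 8 of 8 pairs, by -0.065 ± 0.029 (SE, n = 8 per group). None of these passed adjustment over all isoforms or genes. Among authors' isoforms at an unadjusted p under 0.01, the 233 higher genes with a known length had a median span of 123511 bp, and the 52 lower ones 15118 bp.

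The lists of channel, receptor and postsynaptic genes that lay higher, and of myelin, ribosomal and respiratory genes that lay lower, were weighed against 3 technical explanations. Of 100 random splits of the libraries, the real one included, 3 called at least 14 lists, with 15 as the highest of the other splits. The random splits were not held to 4 libraries of replicates 1 to 4 on each side, as the real split is. A split with 15 lists had that balance. The share of 3 in 100 is therefore not taken among like splits and does not decide whether the count of lists is due to chance. The median of the other splits was 7 lists, which shows how easily the preset correlation gives calls here. With labels swapped within numbered pairs, 10 of 100 swaps called at least the real 15 lists (highest other 18), and 18 of 100 gave at least the real 1330 isoforms at an unadjusted p under 0.05 (highest other 3328), so chance could not be excluded in the paired fit.

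Gene length was weighed next: 6 of the 10 higher lists and 4 of the 4 lower lists lay outside the 95% range of random lists matched on length. Those random lists draw genes independently, so the range is too narrow for lists whose members vary together. The estimated correlation was 0.455 for channels and 0.538 for the respiratory chain. With the length trend removed the channel median was 0.049 and the myelin median -0.088, so length alone is argued against as the whole of these medians. Length together with variation shared by a list's genes is not excluded. The metabotropic and mTOR list is among the 6, at percentile 99.59, although its median went from 0.027 to 0.013 with the length trend removed and its call ended. For the receptor subunit and chromatin lists gene length stays open, since 0 of these lists lay above that range; with the trend removed their medians went from 0.021 to 0.012 and from 0.020 to 0.016. The GABA list lay inside the range too, at percentile 95.77, and its median went from 0.028 to 0.018 with the trend removed while its call held (adjusted p = 0.0299), so length is not settled for it either. The cortical list lay inside the range, at percentile 97.47, and its genes are short, so that the matched median was -0.0021. Its median went from 0.020 to 0.022 and only its call was lost, so the test does not decide.

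The library axis shared with the split of replicates 1 to 4 and 5 to 8 was also weighed. With its score as a covariate, 13 of 14 lists were called in their direction. These calls rest on the preset correlation, which gave a median of 7 lists in the other random splits. The test therefore does not decide whether the axis is the whole cause of the calls. A share of the differences does follow this axis: across genes they correlated at 0.588 with the differences between these sets and at -0.585 with the axis itself, but at only 0.230 between the sets. The call of the chromatin list ended, with a median of 0.0063 (adjusted p = 0.251). Other medians moved too: channels went from 0.069 to 0.032, the respiratory chain from -0.049 to -0.017 and ribosomal proteins from -0.059 to -0.029, while myelin genes went from -0.091 to -0.10 and immediate early genes from 0.050 to 0.070. An effect of kainate on these groups of genes may remain, as a hypothesis that the random splits, the paired swaps, gene length, this axis and the dissection leave unsettled.

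The Nedd4 isoform at the head of the authors' list was weighed next, because it was near 6.78 in all libraries of replicates 5 to 8 and averaged 9.69 in replicates 1 to 4. A loss of total Nedd4 expression is argued against: the total over isoforms differed by 0.10 between these sets. In all, 8 isoforms shifted by over 2 on the log2 scale without overlap, 1 of them in a gene with 1 isoform, which an exchange of reads between isoforms of that gene cannot explain. In the other 7 the median shift was 2.50 and that of the gene total 0.10, a ratio of 0.0415. A minor isoform gives a low ratio whatever the cause, so reads assigned to isoforms differently in the 2 sets of libraries and true isoform differences cannot be told apart here. The kainate difference of the Nedd4 isoform lay within replicates 1 to 4.

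The lower myelin and ependymal lists were weighed against tissue carried along in the dissection, since white matter and ventricle wall border CA1. The SD of the list mean between controls was 1.05 times the group difference for the choroid plexus and ependymal list and 1.12 times for the myelin list. This sets single libraries against a difference of means and does not decide, so a difference in dissection and an effect of kainate cannot be told apart. The most abundant myelin gene, Mbp, was at 17.0 in controls and differed by -0.14. The most abundant ependymal genes, Ccdc153 and Enkur, were both at 9.11 and differed by -0.26 and -0.12. Of the 24 measured myelin genes 3 are also on another list, and of the 11 ependymal genes 0. Slower myelination after kainate stays open and was not tested.

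The higher dentate list and the higher channel, postsynaptic, GABA, receptor subunit and metabotropic lists were weighed against the same explanation. For the dentate list the SD between controls was 0.808 times the group difference, which does not decide. With the library means of the dentate and myelin lists as covariates, 0 of the 5 other lists stayed called. With the dentate mean alone 1 of the 5 did, and with the myelin mean alone 4 of the 5. The test is not specific to tissue: of 21 pairs of other called lists used in the same way, 13 left at most 1 of the 5 called. Dissection and an effect of kainate therefore cannot be told apart for these lists.

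For single features the splits say nothing about chance. The real split called 0 isoforms, 0 genes and 0 usage genes by limma, with 325, 230 and 88 at an unadjusted p under 0.05, and with a real count of 0 all 100 of 100 splits give at least as many in each case by construction. The highest other split called 1 isoform, 0 genes and 684 usage genes. The split with 684 put 7 of the 8 libraries of replicates 1 to 4 on one side, and 42 of 99 other splits called usage genes, which points to the structure of the samples; with the replicate block 0 usage genes were called.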
